A study of Mus musculus with 8 samples.

How the data were processed

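Total RNA was extracted from mouse retina with a QIAGEN RNeasy Micro Kit and sequenced as 150 bp paired-end reads on an Illumina NovaSeq, per the labels' protocols. The labels give retina as the tissue and retinal ganglion cells as the cell type, and the series design states that different mice were used. They do not say which mice went into which library, so p-values measure the spread between these libraries. They give no injury, age, time after injection, cell sorting, batch or library kit, so these are not known here. The submitters' processing notes name fastp for read trimming, HISAT2 for alignment, HTSeq for counting, R 3.2.0 and DESeq2, and the genome builds GRCm38 and mm10. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty.

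The values analysed are FPKM, deposited by the authors as a table of 24860 gene symbols by 8 libraries. The table holds no raw counts, so no count model was run. Each column was matched to its sample by name, with 0 unmatched value columns. Of the symbols, 24027 matched a RefSeq symbol of GRCm38.p6 and 19858 a GENCODE vM21 symbol, from which positions are given where the symbol matched. Depth was estimated from the spacing of low FPKM values in 175 single-exon genes, of which 61 gave the modal depth of about 38000000 counted fragments, and 67.7% of 406 low values were whole multiples within 0.05 of a count. The annotated lengths are therefore inexact, and depth is approximate. No counting interval is therefore given for single values.

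Groups and replicate numbers came from the sample titles. The main test was fitted on log2(FPKM + 1) for the 12858 genes with a mean of at least 1 FPKM over all 8 libraries, with lmFit and eBayes with a trend in limma 3.58.1 (R 4.3.3). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. For FPKM values reported per group, the mean and SD are over n = 4 libraries, and log2 differences are AAV2-shCX36 minus AAV2-scramble on the log2(FPKM + 1) scale with their moderated standard error. The Gjd2 level was also tested with a two-sided exact permutation test over all 70 relabellings, whose smallest p is 0.0286.

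37 gene lists (retinal cell types, other tissues, pathways and gap junction genes) were fixed before the data were examined, as were the main test, the naming rule and the alternatives other than omitted pairs of libraries. 13 of their symbols were not found in the table. Lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the 35 lists tested, and beside it with an estimated correlation and with fry. Some genes stand in more than 1 list: B2m is in the interferon and the housekeeping list, Lgals3 in the axon injury and the microglia list, and 5 of 12 astrocyte and 2 of 18 Müller genes are also in another list. Counts adjusted over the list alone used the members of that list as the only tests.

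Named genes followed a rule with these parts: Gjd2 and every tested connexin and pannexin; the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, passing over unnamed gene models; the 4 members with the smallest p of each passing list; and up to 2 members of any other list with an unadjusted p under 0.05. The rule gave 115 genes. Genes named in addition, such as the class I and chemokine genes among the closing observations, were chosen after their values were seen.

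Alternatives were pseudocounts of 0.1 and 0.5, median-of-ratios scaling, quantile normalization and rescaling to TPM, no filter and a filter of 5 FPKM, the variance model without trend or with robust fitting, library weights, the replicate number as a block, other thresholds, and each library left out in turn. Pairs of libraries left out (AAV2-scramble 1 and 2, AAV2-scramble 3 and 4, AAV2-shCX36 1 and 4) were added after seeing the data. The gene test and the list test were tested on simulated data with 12744 genes past the filter. Of 50 genes changed at each size, 32% were recovered at 1.5-fold, 86% at 2-fold, 82% at 4-fold and 98% at 8-fold, with 2 unchanged genes among 151 calls. A planted list of 25 genes had an adjusted p of 2.67e-34 in camera and 0 of 30 unchanged lists passed. The simulated noise was drawn for each gene separately, so genes of a list did not vary together. In the real data the interferon list had an estimated correlation of 0.776. The simulation therefore cannot tell whether the preset correlation of 0.01 gives sound p-values for such lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.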

Results

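RNA sequencing measured gene expression in 8 libraries of mouse retina, all annotated by the submitters to retinal ganglion cells, the neurons whose axons form the optic nerve. 4 libraries are labelled AAV2-shCX36, for an adeno-associated virus with a short hairpin RNA against connexin 36, a gap junction protein of retinal neurons. The other 4 are labelled AAV2-scramble, the control hairpin. Each library lists 24860 genes in FPKM, a count of fragments scaled by transcript length and by the mapped fragments of the library. The FPKM of a library summed to between 282721 and 294055, and between 12331 and 13089 genes reached 1 FPKM. The spacing of low values in single-exon genes put the depth at about 35900000 to 39000000 counted fragments per library. COX1, a subunit of cytochrome c oxidase encoded in mitochondrial DNA, had the highest FPKM in every library, from 3907 to 6125.

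The single comparison of the design, AAV2-shCX36 against AAV2-scramble with n = 4 each, asks which transcripts differ when connexin 36 is targeted. Gjd2, the gene of connexin 36 (GRCm38 chromosome 2, 114009601 to 114013619, minus strand, protein-coding), was lower after AAV2-shCX36. Its level was 15.6 ± 1.48 FPKM (SD, n = 4) against 27.5 ± 11.3 in AAV2-scramble, or 56.5% of the control mean, a log2 difference of -0.70 ± 0.25 (SE). The AAV2-shCX36 libraries 1 to 4 had 17.0, 14, 14.6 and 16.6 FPKM. The AAV2-scramble libraries 1 to 4 had 38.7, 35.9, 17.4 and 18.2 FPKM, so controls 1 and 2 carried most of the difference. Every AAV2-shCX36 value lay below every control value, which gave a p of 0.0286 in a two-sided exact permutation test over 70 relabellings, the smallest p that 4 against 4 libraries allow. In the limma model across all genes its adjusted p was 0.148. Without AAV2-scramble 1 and 2 the log2 difference was -0.19 (exact p = 0.133), and without AAV2-scramble 3 and 4 it was -1.21 (exact p = 0.0667), where 4 against 2 libraries cannot reach 0.05. Leaving out AAV2-shCX36 library 1, 2, 3 or 4 gave exact p of 0.114, 0.143, 0.143 and 0.114, with log2 differences of -0.74, -0.65, -0.67 and -0.73. Leaving out AAV2-scramble library 1, 2, 3 or 4 gave an exact p of 0.0286 each time, with log2 differences of -0.51, -0.55, -0.88 and -0.86.

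**Figure D1:**
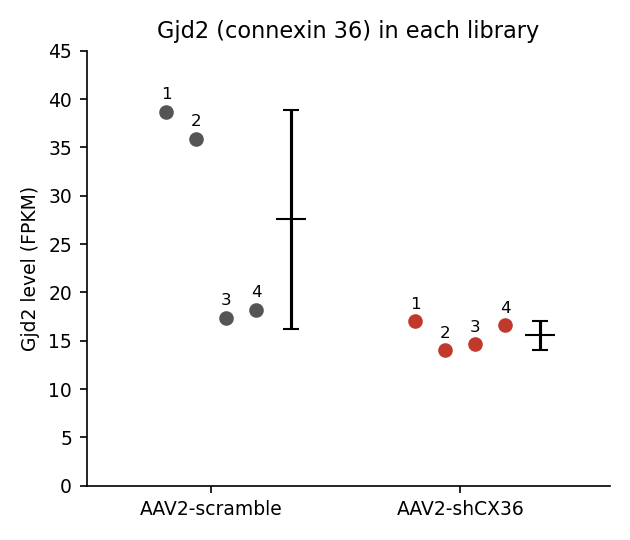
Level of Gjd2 in FPKM (vertical axis) in each library of the AAV2-scramble and AAV2-shCX36 groups; points are libraries labelled by replicate number, and the bar beside each group is its mean with the SD (n = 4). AAV2-shCX36 libraries lie between 14 and 17.0 FPKM, AAV2-scramble 3 and 4 at 17.4 and 18.2, and AAV2-scramble 1 and 2 at 38.7 and 35.9.

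None of the 7 connexins and pannexins with a mean of at least 1 FPKM, Gjd2 included, passed in limma over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and the list had an adjusted p of 0.923. Panx2 had 33.7 ± 1.73 FPKM against 27.1 ± 4.98 (adjusted p = 0.155) and Panx1 8.18 ± 0.448 against 6.95 ± 1.53 (adjusted p = 0.328). Gja10, the connexin 57 gene of horizontal cells, had 7.06 ± 1.78 against 9.45 ± 0.994 FPKM (adjusted p = 0.185). Gja1 (connexin 43), Gja4 and Gjc1 had log2 differences of 0.79, 0.06 and -0.04, with adjusted p of 0.263, 0.923 and 0.904.

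The control libraries did not form a single cluster. The 4 AAV2-shCX36 libraries correlated with one another at 0.986 to 0.991, whereas AAV2-scramble 2 and 4 correlated at 0.946. On the first principal component, with 43.5% of the variance, AAV2-scramble 1 and 2 lay at 25.6 and 36.6, AAV2-scramble 3 and 4 at 5.5 and -3.8, and the AAV2-shCX36 libraries between -20.0 and -8.5. AAV2-scramble 1 and 2 carried more oligodendrocyte transcript, with a mean log2 level of that list of 2.93 and 4.49 against 1.17 and 0.99 in AAV2-scramble 3 and 4. They also carried more of the microglial marker Tmem119, at 48.0 and 47.2 FPKM against 17.1 and 8.0. The labels give no batch, date or litter for these libraries.

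**Figure D2:**
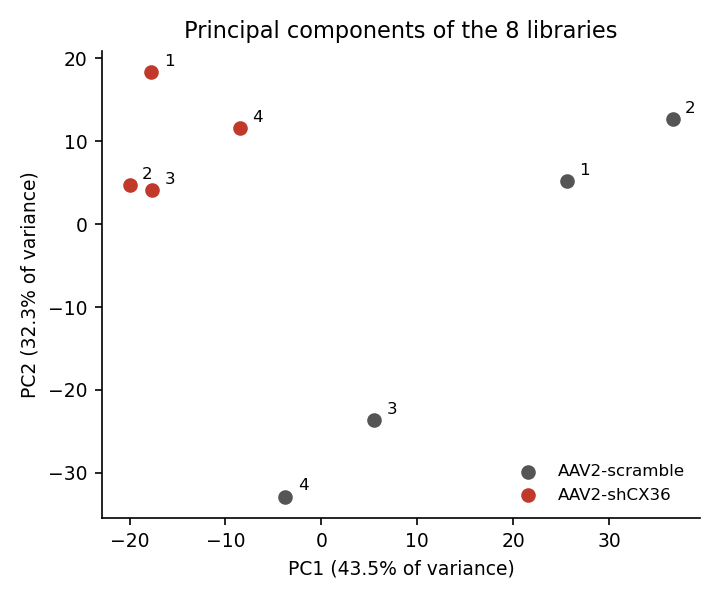
First and second principal components (horizontal and vertical axes, 43.5% and 32.3% of the variance) of log2(FPKM + 1) over the genes tested; points are the 8 libraries labelled by replicate number and coloured by group. AAV2-scramble 1 and 2 lie apart from AAV2-scramble 3 and 4, and the AAV2-shCX36 libraries lie together at the left.

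Of 12858 genes tested, 288 were higher and 324 lower in AAV2-shCX36 at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment. The rises were the larger changes, with 109 genes up at least 2-fold and 11 genes down at least 2-fold. Among the largest rises were Igtp and Gbp6, interferon-inducible GTPases, and Tap1, Cd74 and H2-K1 of antigen presentation. Among the largest falls were Chil3, a chitinase-like myeloid gene, P2ry12 of microglia, Rlbp1 and Glul of Müller glia, and Nrl and Opn1sw of photoreceptors. The groups did not overlap in 2045 genes, where chance gives 2.86% of genes, or 367, and 611 of the 612 called genes were among them. The median log2 difference over all genes was 0.01.

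The counts depended on single libraries. They were 96 higher and 84 lower without AAV2-shCX36 library 1, 101 and 70 without 2, 104 and 107 without 3, and 152 and 168 without 4. They were 186 and 292 without AAV2-scramble library 1, 236 and 182 without 2, 132 and 111 without 3, and 575 and 591 without 4. In alternatives chosen after seeing the data, they were 565 higher and 393 lower without AAV2-scramble 1 and 2, 1542 and 1914 without AAV2-scramble 3 and 4, and 68 and 28 without AAV2-shCX36 1 and 4. None of the 67 named genes past the threshold changed sign in these alternatives, and 28 of them stayed past it with every single library left out. Calb1 passed in none of the 8 omissions, and Bak1, Diablo, Atp1b2, Polr2a and Phgdh passed in 1 (highest adjusted p 0.132, 0.128, 0.113, 0.11 and 0.118). Lgals3, Stmn4, Lrit3, Cyp51 and Kcnj10 passed in 2 (highest 0.11, 0.124, 0.138, 0.0915 and 0.108), B2m, Chac1, Col6a2, Dbp, ND3 and ND5 in 3 (0.128, 0.0944, 0.0835, 0.0944, 0.0999 and 0.101). Opn1sw, Pde6c, Ccl6, Tfap2b, Slc1a2 and Slc1a7 passed in 4 (0.0887, 0.0793, 0.0682, 0.0601, 0.082 and 0.0872), and Nrl, Kcne2, ATP8 and Cplx4 in 5 (0.0577, 0.0804, 0.0639 and 0.0576). Gngt2, Rorb and Slc17a7 passed in 6 (0.0669, 0.0524 and 0.0524), and Rlbp1, Ecel1, Arc and Pde6g in 7 (0.0576, 0.0608, 0.0573 and 0.052).

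Interferon-stimulated and antigen presentation genes rose together after AAV2-shCX36. Of the 30 measured members of this list 28 rose and none fell, with 30 rising when adjusted over the list alone, and the median log2 difference was 2.24. The 2 members short of the threshold over all genes were also higher. In the same libraries the microglia and macrophage list had a median of -0.58, and lens transcripts were highest in AAV2-shCX36 1 and 4. The list passed the camera test with an adjusted p of 7.6e-31, and had an adjusted p = 0.556 with an estimated correlation. Tap1, a pump that loads peptides for class I presentation, rose from 2.67 ± 0.705 to 52.9 ± 15.8 FPKM (SD, n = 4; log2 3.85 ± 0.24 SE, adjusted p = 0.000219). Psmb9, an inducible proteasome subunit, rose from 2.24 ± 1.15 to 23 ± 5.03 FPKM, and its gene overlaps the start of Tap1 on the opposite strand, so some fragments could belong to either.

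The class I genes were abundant. H2-K1 reached 255 ± 55.1 FPKM against 26.8 ± 13.2, H2-D1 365 ± 68.4 against 77.4 ± 21.4, and B2m, the shared light chain, 347 ± 82.3 against 106 ± 57.6 (log2 3.34, 2.25 and 1.90, adjusted p = 0.00225, 0.00122 and 0.0435). Nlrc5, the activator of class I transcription, rose from 0.175 ± 0.123 to 11 ± 3.38 FPKM (adjusted p = 0.000219). Class II transcripts rose as well, with Cd74, the invariant chain, at 87.7 ± 42.8 FPKM against 5.60 ± 2.88 and H2-Aa at 31.4 ± 13.9 against 1.57 ± 1.49 (adjusted p = 0.00168 and 0.00225). The interferon-inducible GTPases Igtp (69.2 ± 24.0 against 3.15 ± 1.79 FPKM), Irgm2 (31.1 ± 9.08 against 2.04 ± 0.926), Gbp6 (26.9 ± 10.4 against 0.674 ± 0.263) and Gbp2 (27.8 ± 16.5 against 1.89 ± 1.24) rose by log2 4.12, 3.40, 3.99 and 3.27. Igtp and Irgm2 overlap on chromosome 11, and H2-Q4 (log2 3.50), Gbp6 and Gbp2 have near-identical relatives, so the values of these genes individually are uncertain. The count of rising members was 18 without AAV2-shCX36 library 1 and 17 without library 2, and at least 19 without any other single library. It was 29 of 30 without AAV2-scramble 1 and 2, 28 of 30 without AAV2-scramble 3 and 4, and 19 of 29 without AAV2-shCX36 1 and 4.

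**Figure D3:**
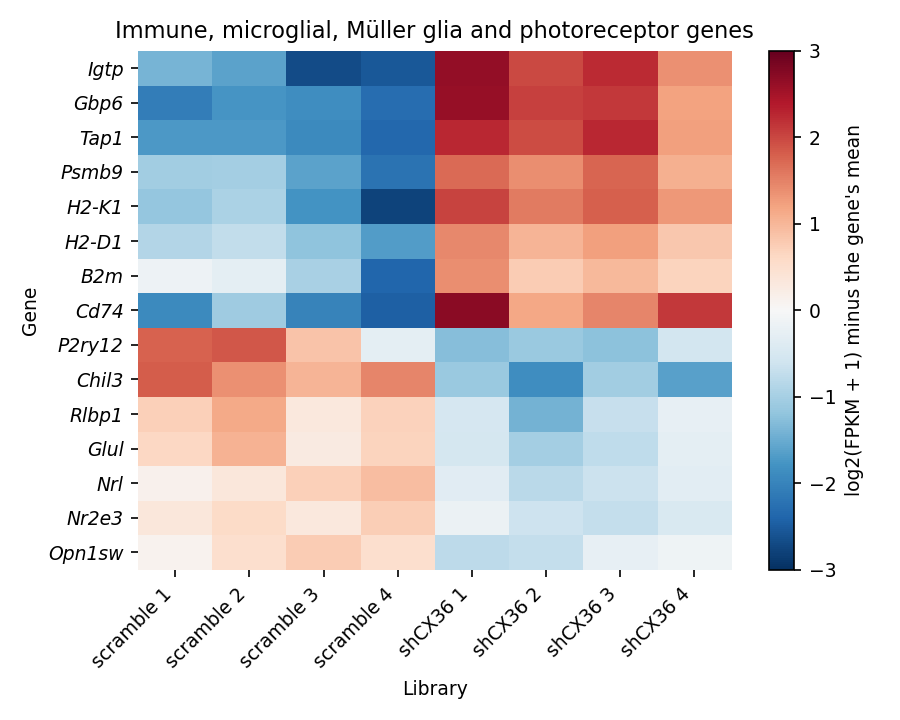
Levels of 15 genes (rows) in the 8 libraries (columns); colour is log2(FPKM + 1) minus the mean of the gene over all libraries, with the colour scale ending at 3 above and below that mean. Genes from Igtp to Cd74 are higher, and genes from P2ry12 to Opn1sw lower, in every AAV2-shCX36 library than in every AAV2-scramble library.

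Photoreceptor genes fell after AAV2-shCX36. Of 20 rod genes 16 fell and none rose, with 19 falling when adjusted over the list alone and a median log2 difference of -0.70. The rod list had an adjusted p of 6.77e-17 in camera and an adjusted p = 0.556 with an estimated correlation. Nrl, the transcription factor that specifies rods, fell from 77.7 ± 19.3 to 36.6 ± 6.19 FPKM (log2 -1.05 ± 0.18, adjusted p = 0.0164), and its target Nr2e3 from 38.7 ± 5.60 to 19.1 ± 3.27 (log2 -0.98, adjusted p = 0.00664). Pde6g, a subunit of the rod phosphodiesterase, fell from 314 ± 50 to 175 ± 25.6 FPKM, Rom1 from 275 ± 26.5 to 170 ± 20.6 and Cngb1 from 19.6 ± 1.54 to 12.1 ± 1.74 (adjusted p = 0.0144, 0.0108 and 0.0111). Of 14 cone genes 4 fell and none rose, with 13 falling when adjusted over the list alone, a median of -0.59, an adjusted p of 4.99e-09, and an adjusted p = 0.621 with an estimated correlation. The 4 were Opn1sw, the short-wavelength cone opsin, at 620 ± 138 FPKM against 1182 ± 212, Pde6c at 128 ± 16.8 against 220 ± 42.8, Gngt2 at 115 ± 23 against 200 ± 22, and Kcne2 at 66.3 ± 14.7 against 127 ± 25.2. In the same libraries the ganglion cell marker list had a median of 0.27. The count of falling rod genes was 6, 6 and 6 without AAV2-shCX36 library 1, 2 or 3 and 5 without AAV2-scramble library 3, and of falling cone genes 0, 1, 0 and 9 without AAV2-shCX36 library 1 or 2 or AAV2-scramble library 3 or 1. Without AAV2-scramble 1 and 2 the rod and cone counts were 18 and 9, without AAV2-scramble 3 and 4 they were 16 and 6, and without AAV2-shCX36 1 and 4 they were 3 and 0.

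Genes of Müller glia, the radial support cells of the retina, were lower as a list. Of 18 Müller genes 15 were lower and 3 higher. Past the threshold 7 fell and none rose, with 11 falling when adjusted over the list alone and a median of -0.72. The adjusted p was 1.58e-08 in camera, and the list had an adjusted p = 0.729 with an estimated correlation. Glul, glutamine synthetase, fell from 416 ± 91.0 to 169 ± 36.2 FPKM (log2 -1.29 ± 0.19, adjusted p = 0.00897). Rlbp1, the retinaldehyde-binding protein, fell from 35.8 ± 8.76 to 13.0 ± 4.37 FPKM (log2 -1.43, adjusted p = 0.0184), and Abca8a from 16.6 ± 4.28 to 5.66 ± 1.35 (log2 -1.40, adjusted p = 0.00875). Spc25, a kinetochore gene used as a Müller marker, fell from 21.1 ± 5.35 to 4.45 ± 0.947 FPKM, and the potassium channel gene Kcnj10 from 5.64 ± 1.88 to 2.24 ± 0.598 (adjusted p = 0.00112 and 0.0372). The count of 7 was 3 or 4 without any 1 of the AAV2-shCX36 libraries or AAV2-scramble library 1 or 2, 4 without AAV2-scramble 1 and 2 together, 11 without AAV2-scramble 3 and 4, and 3 without AAV2-shCX36 1 and 4.

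Transcripts encoded in mitochondrial DNA were lower in the same direction, and their share of all FPKM was 3.79% to 4.83% in AAV2-shCX36 libraries against 5.32% to 6.57% in controls. Of 13 genes 7 fell and none rose, with 12 falling when adjusted over the list alone and a median of -0.51. The adjusted p was 2.16e-10 in camera, with an adjusted p = 0.556 with an estimated correlation. ND6 fell from 100.2 ± 3.16 to 65.6 ± 5.34 FPKM and ND5 from 1501 ± 150 to 1034 ± 88.9 (log2 -0.61 and -0.54, adjusted p = 0.00238 and 0.0300). ND3 and ATP8 fell by 0.82 and 0.62 on the log2 scale. Nuclear-encoded oxidative phosphorylation genes had a median of 0.03, with none of 47 passing in limma over all genes or adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.623 for the list). The count of 7 was 1 to 3 without any 1 of the AAV2-shCX36 libraries or AAV2-scramble library 2 or 3, 7 and 8 without each pair of controls, and 1 without AAV2-shCX36 1 and 4.

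**Figure D4:**
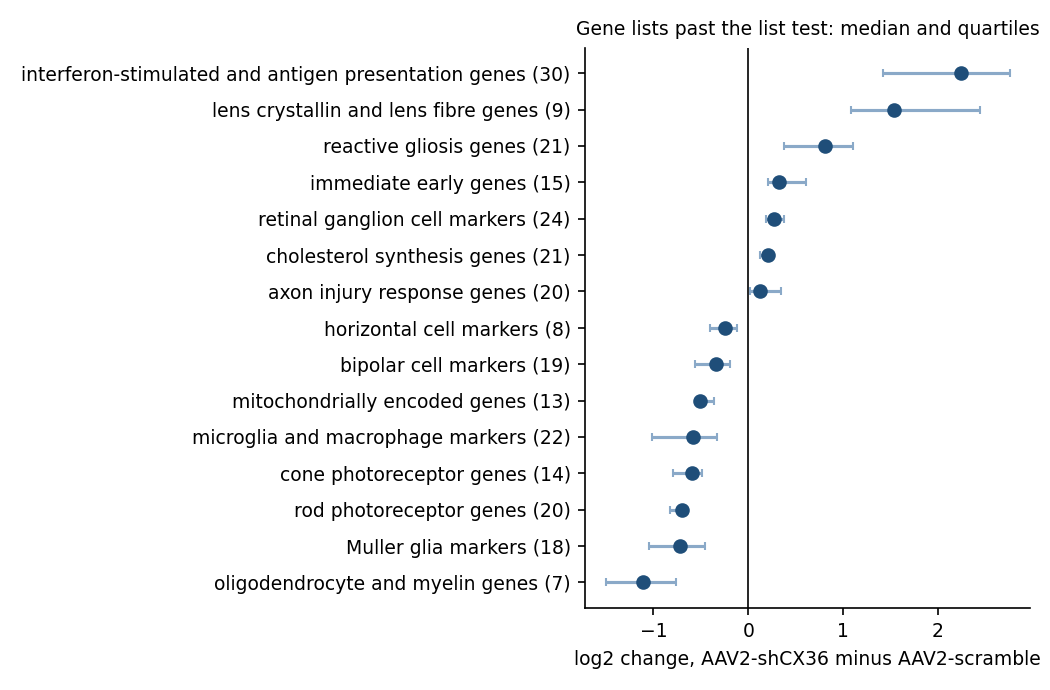
Median (points) and quartiles (bars) of the log2 difference, AAV2-shCX36 minus AAV2-scramble (horizontal axis), over the measured members of the 15 gene lists that passed the camera test with a preset correlation; the number of members is in parentheses. Medians run from 2.24 for interferon-stimulated genes to -1.11 for myelin genes.

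The reactive gliosis list was higher and the microglia list lower, with few single calls. Of 21 gliosis genes 3 rose and none fell, with 11 rising when adjusted over the list alone, a median of 0.81, an adjusted p of 7.98e-06, and an adjusted p = 0.768 with an estimated correlation. The 3 were Stat3 (40.2 ± 5.37 against 22.5 ± 2.77 FPKM, adjusted p = 0.00807), the complement gene C4b (15.7 ± 9.19 against 2.72 ± 2.97, adjusted p = 0.0427) and the serine protease inhibitor gene Serpina3n (50.2 ± 29.4 against 19.1 ± 0.664, adjusted p = 0.0473). C3, the central complement component, rose from 1.18 ± 0.632 to 55.7 ± 80.9 FPKM (log2 3.74 ± 0.77, adjusted p = 0.0308), with AAV2-shCX36 library 1 at 177 FPKM and the others of its group between 9.84 and 24.6. With single libraries left out, C4b passed only without AAV2-scramble library 2 or 4, Serpina3n only without AAV2-shCX36 library 1, and C3 only without AAV2-shCX36 library 1 or 3 or AAV2-scramble library 4. The highest adjusted p were 0.114 for C4b, 0.101 for Serpina3n and 0.0779 for C3.

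Of 22 microglia and macrophage genes, Cd74 and Lgals3 rose and P2ry12 fell, with 2 rising and 3 falling when adjusted over the list alone. The median was -0.58, the adjusted p 0.00849, and the list had an adjusted p = 0.855 with an estimated correlation. P2ry12, the ADP receptor of resting microglia, fell from 26.2 ± 15.1 to 4.57 ± 1.42 FPKM (log2 -2.10 ± 0.43, adjusted p = 0.0302). Its control values were 37.5, 39.8, 19.3 and 8.22 FPKM in AAV2-scramble 1 to 4, and with single libraries left out it passed only without AAV2-scramble 4, with an adjusted p of up to 0.098. The list had an adjusted p of 0.895 without AAV2-scramble 1 and 2. Other myeloid genes moved in opposite directions. Arg1, arginase 1, rose from 0.250 ± 0.125 to 13.5 ± 4.90 FPKM (log2 3.47 ± 0.25, adjusted p = 0.000376), whereas the chitinase-like gene Chil3 fell from 9.59 ± 2.40 to 0.502 ± 0.399 (log2 -2.83 ± 0.22, adjusted p = 0.000518) and the chemokine gene Ccl6 from 6.17 ± 2.77 to 1.52 ± 0.499 (log2 -1.45, adjusted p = 0.0213).

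Retinal ganglion cell markers passed as a list without any single call. None of 24 passed in limma over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05, 7 of them higher. In all, 21 were higher in AAV2-shCX36, the median was 0.27, the adjusted p 0.00253, and the list had an adjusted p = 0.855 with an estimated correlation. Rbpms, a pan-ganglion-cell marker, had 64.9 ± 5.35 FPKM against 46.4 ± 8.72 (adjusted p = 0.0672) and Nefm 264 ± 16.4 against 202 ± 42.7 (adjusted p = 0.140), while Nefh had 44.0 ± 4.8 against 75.1 ± 27.1 (adjusted p = 0.123). The mean log2 level of the list was 5.65 and 5.31 in AAV2-scramble 1 and 2 and 5.86 and 6.0 in AAV2-scramble 3 and 4. Without AAV2-scramble 1 and 2 the camera direction turned and the adjusted p was 0.927.

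Axon injury response genes included 3 that rose among 20, both over all genes and adjusted over the list alone, with none falling, a median of 0.13, an adjusted p of 0.0366, and an adjusted p = 0.646 with an estimated correlation. Ecel1, an endopeptidase gene induced by nerve injury, rose from 0.115 ± 0.115 to 3.10 ± 1.96 FPKM, Lgals3 (galectin 3) from 1.89 ± 0.570 to 5.32 ± 2.09, and the tubulin-binding Stmn4 from 35.3 ± 4.47 to 46.4 ± 2.17 (adjusted p = 0.0190, 0.0416 and 0.0435). Of 15 immediate early genes Arc and Egr4 rose and none fell, with 4 rising when adjusted over the list alone and a median of 0.32. This list had an adjusted p of 0.00928, and an adjusted p = 0.855 with an estimated correlation. Arc rose from 1.97 ± 0.759 to 6.93 ± 2.29 FPKM and Egr4 from 0.717 ± 0.305 to 2.57 ± 0.608 (log2 1.41 and 1.06, adjusted p = 0.0151 and 0.0130). Of 21 cholesterol synthesis genes Cyp51, lanosterol demethylase, rose from 19.2 ± 1.02 to 24.0 ± 1.26 FPKM (adjusted p = 0.0272) as the 1 call over all genes and adjusted over the list alone. The list median was 0.21, with an adjusted p of 0.000941 and an adjusted p = 0.786 with an estimated correlation. Without AAV2-scramble 3 and 4 the axon injury list had an adjusted p of 0.538 and the immediate early list 0.820 with its direction turned, and without AAV2-scramble 1 and 2 the cholesterol list had 0.524.

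Bipolar and horizontal cell markers were lower as lists, each with 1 call. Lrit3, which acts at synapses onto bipolar cells, fell from 33.4 ± 6.10 to 21.9 ± 2.82 FPKM (adjusted p = 0.0448), and Calb1, calbindin, fell from 91.1 ± 3.66 to 64.7 ± 12.1 (adjusted p = 0.0472). Calb1 did not pass with any 1 of the 8 libraries left out (adjusted p = 0.0523 to 0.134). When adjusted over the list alone 2 of 19 bipolar and 2 of 8 horizontal cell genes fell, with medians of -0.34 and -0.24. Their adjusted p were 0.00746 and 0.00928, with adjusted p = 0.786 with an estimated correlation for both. Bipolar levels differed within the controls, with list means of 4.21 and 4.38 in AAV2-scramble 1 and 2 against 3.00 and 3.32 in AAV2-scramble 3 and 4, and without AAV2-scramble 1 and 2 the direction turned (adjusted p = 0.895). Lrit3 did not follow the list there, at 26.8, 39.3, 37.8 and 29.7 FPKM in AAV2-scramble 1 to 4, so its fall need not reflect bipolar cells. Of 14 amacrine genes Tfap2b fell from 16.3 ± 0.647 to 11.1 ± 1.55 FPKM (adjusted p = 0.0176), the 1 call also when adjusted over the list alone, and the list had a median of -0.21 and an adjusted p of 0.0507.

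Lists of tissue that can accompany retina also differed between libraries. None of 9 lens genes passed in limma over all genes, 6 had an unadjusted p under 0.05 and 6 rose when adjusted over the list alone, with a median of 1.53, an adjusted p of 0.00253, and an adjusted p = 0.744 with an estimated correlation. Cryaa, the lens alpha crystallin, was at 109, 5.79, 11.3 and 236 FPKM in AAV2-shCX36 1 to 4 and at 0.11, 0.14, 3.59 and 7.72 in AAV2-scramble 1 to 4, and without AAV2-shCX36 1 and 4 the lens list had an adjusted p of 0.0808. None of 7 oligodendrocyte genes passed in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, with a median of -1.11, an adjusted p of 0.0195, and an adjusted p = 0.834 with an estimated correlation. Without AAV2-scramble 1 and 2 the direction of the list turned (adjusted p = 0.896). The lymphocyte list and the list of muscle and cornea genes had 1 of 14 and 2 of 11 members with a mean of at least 1 FPKM and were not tested.

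The other lists did not pass. Voltage-gated ion channel genes had an adjusted p of 0.0507 with a median of 0.17, 2 falling over all genes, among them Kcnv2 by 0.76 on the log2 scale, and 3 rising and 2 falling when adjusted over the list alone. Extracellular matrix genes had an adjusted p of 0.0566, with Col6a2 rising from 6.72 ± 1.08 to 9.96 ± 0.424 FPKM, a call that held in 3 of the 8 omissions of a single library, and 4 rising when adjusted over the list alone. Among 37 synaptic genes (adjusted p = 0.182), 3 fell and 1 rose over all genes, with 5 falling and 4 rising when adjusted over the list alone. The photoreceptor and bipolar ribbon synapse genes Stx3 and Cplx4 fell from 47.6 ± 5.84 to 31.2 ± 3.2 and from 124 ± 15.5 to 80.6 ± 8.39 FPKM. Of 25 glutamate receptor and transporter genes (adjusted p = 0.705), 3 fell, among them Slc17a7 and Slc1a7 by 0.68 and 0.49, and 4 fell and 2 rose when adjusted over the list alone. The median of this list was 0.11 and its mean -0.003, and camera gave the direction as up.

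Of 8 astrocyte genes (adjusted p = 0.200) 3 fell, among them Slc1a2 and Atp1b2 by 0.54 and 0.47, and 3 fell and 1 rose when adjusted over the list alone. Of 24 apoptosis genes (adjusted p = 0.923) Bak1 and Diablo rose by log2 0.35 and 0.28 and 1 fell, with 2 rising and 3 falling when adjusted over the list alone. Of 23 unfolded protein and integrated stress response genes (adjusted p = 0.705) Chac1 and Phgdh rose by 0.68 and 0.71, Chac1 passing in 3 and Phgdh in 1 of the 8 omissions of a single library, with 2 rising when adjusted over the list alone. This list had a median of -0.01, a mean of 0.04 and the camera direction up. Of 16 circadian genes (adjusted p = 0.923) 2 rose and 1 fell, likewise 2 and 1 when adjusted over the list alone, among them Dbp rising by 0.29 and Rorb falling by 0.40. Of 22 glycolysis genes (adjusted p = 0.923) Hk2, hexokinase 2, fell from 56.0 ± 7.86 to 31.4 ± 3.07 FPKM, the 1 call also when adjusted over the list alone. The glycolysis list had a median of 0.03 and a mean of -0.05, with the camera direction down, and the circadian list a median of -0.004 and a mean of 0.002, with the direction down. Of 15 housekeeping genes (adjusted p = 0.837) B2m rose and Polr2a fell, the latter from 42.7 ± 1.91 to 34.7 ± 2.15 FPKM, with 1 rising and 2 falling when adjusted over the list alone.

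No member passed in limma over all genes in the lists of cytosolic ribosomal proteins (43 genes, adjusted p = 0.207), GABA and glycine receptors (20, 0.705), neurotrophic factors and growth signalling (29, 0.837) and endothelial cells and pericytes (16, 0.730), and none did when adjusted over the list alone. At an unadjusted p under 0.05 these lists had 3, 7, 5 and 0 genes. None passed over all genes among 14 dopamine and nitric oxide genes (adjusted p = 0.941), of which 2 rose and 2 fell when adjusted over the list alone, nor among 3 pigment epithelium genes (adjusted p = 0.705), of which 1 rose on that adjustment, and these lists had 5 and 2 genes at an unadjusted p under 0.05. Among 3 blood cell genes (adjusted p = 0.5) none passed on either adjustment and 0 had an unadjusted p under 0.05, and the mean log2 level of that list was 0.33 and 0.31 in AAV2-scramble 1 and 2 and 2.83 and 2.66 in AAV2-scramble 3 and 4.

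Of the 35 lists tested 15 passed camera with a preset correlation of 0.01, 7 up and 8 down, and 0 of the 35 passed camera with an estimated correlation, where 3 had an unadjusted p under 0.05. The interferon, rod and mitochondrial lists also passed fry, with adjusted p of 0.013, 0.0239 and 0.0239, a test of whether the genes of a list move on balance in a single direction.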

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

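All weighing tests in this part were chosen after the results they bear on had been seen. The 612 genes that differed between the groups are more than any of the other 34 ways to split the 8 libraries into 4 and 4 gave. The real split was the 1 of 35 to call as many, the smallest share that these splits allow. The highest of the others called 0 genes at an adjusted p under 0.05 in limma. Every other split mixes the groups, so a real group difference would widen the spread within its sides and lower its count. The 0 calls therefore add nothing to the rank. A rank of 1 of 35 makes chance an unlikely source of the count but does not exclude it.

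The rise of interferon and antigen presentation genes, with a median log2 difference of 2.24, is the strongest pattern. A larger share of microglia would need their other markers to rise alike, and the list without Cd74 differed by -0.66 ± 0.43 (SE) on the log2 scale, with an exact permutation p of 0.229. Within the controls, lower Gjd2 did not go with a higher interferon level. AAV2-scramble 3 and 4, with Gjd2 close to that of AAV2-shCX36, had list levels of 1.80 and 1.55, below 2.44 and 2.60 in AAV2-scramble 1 and 2. The higher of them lay 1.92 below the lowest AAV2-shCX36 library at 3.71. Over all libraries, AAV2-shCX36 had both the lowest Gjd2 and the highest interferon levels. Gjd2 in the controls could follow bipolar content, so these controls cannot decide whether Gjd2 sets the interferon level. Of the 14 genes of the lymphocyte list, 7 were higher in every AAV2-shCX36 library than in every control. Chance gives 1.43% of genes, or 0.2, and the genes of these libraries at such levels give 4.38%, or 0.613. Lymphocytes in the tissue may be a source of the interferon signal, but their transcripts alone do not show it, and this was not tested. Of the 7, Ccl5 was also measured in controls, at 0.29 to 1.19 FPKM. Ifng was at 0 in AAV2-shCX36 2 and 3, whose interferon list levels were 4.22 and 4.42, above 3.71 in AAV2-shCX36 4. Ifng was so low, at 0.07 FPKM in AAV2-shCX36 4, that a value of 0 does not show its absence. A response to loss of connexin 36 and a response to the hairpin or vector preparation itself both stay open, because the design has no untreated retina and no further hairpin.

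Photoreceptor and Müller glia genes were lower in AAV2-shCX36, in libraries annotated to ganglion cells. An equally lower share of every cell type other than ganglion cells would lower their markers alike. The rod list differed by more than the amacrine list, by -0.56 ± 0.15 (SE, exact permutation p = 0.0286, the smallest possible). This argues against an equal loss of rods and amacrine cells as the whole cause. The amacrine list had a median of -0.21, the smallest fall beside horizontal (-0.24), bipolar (-0.34), cone (-0.59) and Müller (-0.72) lists. Unequal losses of these cell types stay open. A lower share of rods alone would move all rod genes by a single factor. Their 20 log2 differences had an SD of 0.18 against a median standard error of 0.15, with Nrl at -1.05. That standard error includes variation between libraries that rod genes share (estimated correlation 0.665), which does not spread the differences between genes. Setting the SD against it therefore cannot decide whether a single factor holds. Fewer rod transcripts carried into the samples and lower expression in rods cannot be told apart. A biological effect of connexin 36 knockdown, or of the inflammation measured alongside, was not tested and stays open.

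Gjd2 was lower in AAV2-shCX36, and AAV2-scramble 1 and 2 stood far above AAV2-scramble 3 and 4. The higher interferon level of AAV2-scramble 3 and 4 was 1.80, against at least 3.71 in AAV2-shCX36. That difference was found with these labels, so it is no independent check of them. It argues against a wrong label on AAV2-scramble 3 and 4 only if every AAV2-shCX36 library has a high interferon level. Their Gjd2, at 17.4 and 18.2 FPKM, lay just above the 14 to 17.0 FPKM of AAV2-shCX36 and does not settle the labels. Bipolar cells express Gjd2 and their list was higher in AAV2-scramble 1 and 2, yet Gjd2 minus the bipolar list level still differed by -0.34 ± 0.10 (SE, exact permutation p = 0.0286), with 0.54 to 0.78 in AAV2-shCX36 and 0.83 to 1.20 in controls. Amacrine cells, whose AII type also expresses Gjd2, would need their list to fall by about the 0.70 of Gjd2. Its median was -0.21, and the SD of 0.27 over its 14 members is a spread between genes, not an error of the list change. List levels were 3.68 and 3.73 in AAV2-scramble 1 and 2 and 3.53 and 3.63 in AAV2-scramble 3 and 4. Gjd2 minus this list differed by -0.53 ± 0.27 (SE) and overlapped between the groups (exact permutation p = 0.0857). The list fell by less than Gjd2, but a lower share of amacrine cells as the whole cause is not excluded. Part of the split in the controls could follow bipolar content, and the amacrine list does not separate the AII type. A batch stays open because the labels give none, and knockdown was not tested against these.

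Of 300 groups of 4 values checked (35 list levels and 115 named genes in each group), 12 had a library far from the other 3, where chance gives about 1 in 20, or 15. The microglia list level was 4.35 in AAV2-shCX36 4 against 3.85 to 3.89 in the others of its group, and the gliosis list level was 3.75 in AAV2-shCX36 1 against 2.71 to 2.84. In AAV2-shCX36 1, C3 was at 177 FPKM against 9.84 to 24.6, Serpina3n at 94.2 against 33.9 to 37.9, and Panx1 at 7.51 against 8.31 to 8.46. In AAV2-shCX36 2, Gabbr1 was at 83.9 FPKM against 79.3 to 79.8, Ldha at 105 against 113 to 114, Stx3 at 26.5 against 32.5 to 33.1 and Kcnv2 at 13.7 against 18.2 to 18.7. In AAV2-shCX36 4, Rpl34 was at 24.9 FPKM against 20.5 to 20.9. In AAV2-scramble 4, the lens gene Crygs was at 5.35 FPKM against 0.0276 to 0.175.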

How the results depend on the processing

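All alternatives but the omission of pairs of libraries were planned. The 612 called genes kept their sign under both other pseudocounts, median-of-ratios scaling, quantile normalization and rescaling to TPM, and the higher share of calls was 47.1% as reported and 39.6% to 50.4% under these scalings. Of the 67 named genes past the threshold none reversed in any alternative, and 34 to 64 stayed past it when a single library was left out. With no filter 35 stayed and 32 did not, among them Nrl, Opn1sw, Rlbp1, B2m and C3, and with the replicate block 33 stayed and 34 did not. The interferon, rod, cone, Müller glia, mitochondrial, gliosis, cholesterol and lens lists passed camera with every single library left out. Depth of about 38000000 counted fragments limits only low genes, and the self-test found 32% of 1.5-fold changes at this sample size. The cause was not tested for the changes that follow.

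Genes higher and lower numbered 177 and 134 with no filter, 571 and 582 at an adjusted p under 0.10, 96 to 575 and 70 to 591 with a library left out, 565 higher without AAV2-scramble 1 and 2, 1542 and 1914 without AAV2-scramble 3 and 4, and 68 and 28 without AAV2-shCX36 1 and 4. The Gjd2 difference was -0.882 to -0.511 with a library left out (exact p = 0.0286 without 1 of the AAV2-scramble libraries, 0.114 to 0.143 without 1 of the AAV2-shCX36 libraries). It was -0.186 without AAV2-scramble 1 and 2, -1.213 without AAV2-scramble 3 and 4 and -0.809 without AAV2-shCX36 1 and 4, where 4 against 2 libraries cannot pass. Libraries with the same number did not deviate together (correlations 0.128, -0.302, 0.226 and -0.269), so the numbers do not pair them, and not every library correlated best with its own number. With the replicate block 107 genes were higher and 57 lower, Gjd2 was at -0.70 (exact p = 0.125, the smallest that 4 pairs allow), and the amacrine and matrix lists passed at 0.038 and 0.0434.

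Of 35 lists 0 passed camera with an estimated correlation (3 at an unadjusted p under 0.05) and 3 passed fry. With an estimated correlation the adjusted p were 0.556 (interferon, rod and mitochondrial), 0.621 (cone), 0.646 (axon injury), 0.729 (Müller), 0.744 (lens), 0.768 (gliosis), 0.786 (cholesterol, bipolar and horizontal), 0.834 (oligodendrocyte) and 0.855 (ganglion cell, microglia and immediate early). With fry they were 0.0596 (cone), 0.0846 (axon injury), 0.125 (Müller), 0.155 (lens), 0.169 (gliosis and cholesterol), 0.255 (horizontal), 0.37 (bipolar), 0.377 (immediate early), 0.391 (ganglion cell and oligodendrocyte) and 0.622 (microglia). Extracellular matrix passed at 0.0346 under median-of-ratios scaling, 0.0487 under quantile normalization and 0.0253 with no filter. Ribosomal genes passed at 0.0195 under quantile normalization, amacrine at 0.0444 under TPM and 0.0174 with no filter, and ion channels at 0.0122 with no filter. With a filter of 5 FPKM astrocyte genes passed at 0.00132, while axon injury and oligodendrocyte genes had 0.113 and immediate early genes 0.267.

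Without AAV2-scramble 1 and 2 the adjusted p were 0.895 for bipolar (reversed) and microglia, 0.896 for oligodendrocyte (reversed), 0.927 for ganglion cell (reversed), 0.524 for cholesterol, 0.0726 for lens, 4.22e-05 for blood, 2.26e-05 for endothelial, 0.000132 for matrix and 0.0177 for nuclear oxidative phosphorylation genes (reversed). Without AAV2-scramble 3 and 4 they were 0.538 for axon injury, 0.127 for horizontal, 0.82 for immediate early (reversed), 0.00237 for endothelial (reversed) and oxidative phosphorylation, 0.0132 for synaptic and 0.0227 for ion channel genes. Without AAV2-shCX36 1 and 4 they were 0.0781 for immediate early, 0.0808 for lens, 0.0115 for amacrine, 0.000125 for ribosomal, 0.0249 for synaptic and 0.00279 for ion channel genes.

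With a single library left out the adjusted p ranged over 0.00985 to 0.179 for amacrine, 0.0191 to 0.179 for axon injury, 9.09e-05 to 0.0672 for bipolar, 0.00985 to 0.96 for ribosomal, 0.00692 to 0.496 for matrix, 0.000959 to 0.0631 for horizontal, 0.000195 to 0.179 for immediate early, 1.08e-07 to 0.0668 for microglia, 0.041 to 0.927 for oxidative phosphorylation, 0.00325 to 0.268 for oligodendrocyte, 1.5e-05 to 0.065 for ganglion cell, 0.044 to 0.5 for synaptic and 0.0104 to 0.176 for ion channel genes.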

Other observations

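The gene families in this part were chosen after the results had been seen, as 18 families defined by gene symbol, and their tests describe the same libraries. All 5 inducible proteasome subunits and activators rose, from log2 2.94 for Psmb9 and 2.67 for Psmb8 to 0.86 for Psme1 and 0.62 for Psme2, whereas none of 14 other 20S proteasome subunits passed in limma, 3 had an unadjusted p under 0.05, and their median was 0.11, although 12 were higher and their family passed camera (adjusted p = 0.0352, and 0.499 with an estimated correlation). Of 11 class I heavy chain genes 9 rose with a median of 1.97, among them the non-classical H2-T23 (59.8 ± 17.0 against 10 ± 5.20 FPKM, SD, n = 4) and H2-T22 (23.8 ± 5.31 against 4.44 ± 0.381). All 4 Ifit genes, 7 of 8 guanylate-binding proteins and 7 of 8 immunity-related GTPases rose, with medians of 2.56, 2.39 and 2.56. Of 5 tested class II chains 3 rose, with a median of 3.09. Medians of these families kept their sign under median-of-ratios, quantile and TPM scaling. In camera the adjusted p over the 18 families was 1.13e-11 for class I, 2.15e-10 for guanylate-binding proteins, 8.7e-11 for the GTPases, 4.01e-06 for Ifit genes, 6.91e-06 for class II and 3.64e-08 for the inducible subunits. With an estimated correlation, adjusted p = 0.0966 for these families and 0.109 for class II. Relatives within these families share sequence, so the split between members is uncertain.

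Of 11 complement genes C3, C4b, Cfb, C1ra and Serping1 rose, while the microglial C1qa had 62.3 ± 13.5 FPKM against 106 ± 59.4 (adjusted p = 0.485). AAV2-shCX36 1 raised the group means, with Cfb at 34.1 FPKM against 2.68 to 4.26 and C1ra at 14.5 against 1.94 to 4.00 in the others of its group, as with C3. The complement family had a median of 1.38, an adjusted p of 0.00294, and an adjusted p = 0.304 with an estimated correlation. Of 15 Ccl and Cxcl chemokine genes Ccl5, Ccl7, Ccl8 and Ccl24 rose and Ccl6 fell (adjusted p = 0.108 for the family). Ccl8 was at 2.58 ± 1.31 FPKM against 0.0126 ± 0.0251 and Ccl24 at 3.58 ± 1.99 against 0.00961 ± 0.0111. Il1b, interleukin 1 beta, rose from 0.608 ± 0.538 to 5.37 ± 2.53 FPKM and Cd274, the PD-L1 gene, from 0.941 ± 0.284 to 9.76 ± 3.42 (adjusted p = 0.0132 and 0.00225). Of 20 cytosolic aminoacyl-tRNA synthetase genes 19 were higher and Cars and Wars rose, with a median of 0.21, an adjusted p of 1.78e-06, and an adjusted p = 0.109 with an estimated correlation.

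T cell and cytotoxic transcripts appeared at low levels in AAV2-shCX36. Cd3e was at 0.17, 0.04, 0.12 and 0.19 FPKM in AAV2-shCX36 1 to 4, Gzma (granzyme A) at 3.48, 1.15, 0.55 and 1.06, and Nkg7 at 0.97, 1.08, 0.40 and 0.36. These 3 genes were listed at 0 in all 4 AAV2-scramble libraries, as were 9 of the 14 genes of the lymphocyte list, of which 6 were above 0 in all 4 AAV2-shCX36 libraries. Ifng itself was at 0.78, 0.00, 0.00 and 0.07 FPKM in AAV2-shCX36 1 to 4 and at 0 in every control.

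Xist, expressed from an inactive X chromosome, and the Y-linked Ddx3y were both present in every library. Xist was at 24.2, 14.6, 43.4 and 41.6 FPKM in AAV2-shCX36 1 to 4 and at 41.0, 13.9, 48.4 and 5.99 in AAV2-scramble 1 to 4. Ddx3y was at 4.59, 6.83, 3.13 and 2.35 FPKM in the former and at 7.05, 11.4, 2.47 and 8.70 in the latter. The labels give no sex.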
